A study of Drosophila melanogaster with 80 samples.

How the data were processed

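Whole larvae, adult females and adult males of Drosophila melanogaster were kept either at a constant 19 °C or under a daily cycle around the same mean with an amplitude of 8 °C, so that the fluctuating animals passed between 27 °C and 11 °C. Animals were sampled at the high and at the low point of the cycle, and constant-temperature animals were sampled at the same points. Larvae were treated for 7 days and sampled after 6 cycles. Adults were treated for 13 days, were moved to fresh food every second day, and were sampled after 6 and after 12 cycles. The design text gives 4 biological replicates per group, which makes 20 groups of 4 and 80 libraries. Adult replicates are numbered 1 to 4 at 6 cycles and 5 to 8 at 12 cycles. Every column of the count table was used.

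RNA was reverse transcribed from oligo(dT)-selected transcripts and sequenced, per the labels' protocols. Reads were checked with FastQC, trimmed with Trimmomatic, aligned with HISAT2 to the fly genome assembly BDGP6 and assembled and quantified with StringTie, per the submitters' processing notes. The versions of these tools are not given in the sources used here. The deposited values are estimated counts per gene, not scaled to library size, for 17697 gene identifiers, and they were rounded to whole numbers before testing. Of these identifiers, 17559 matched a gene of the BDGP6.54 annotation (release 115) and 138 did not. Coordinates are from that annotation, 1-based. A total of 206 genes had no count in any library. The labels give no strand information, so counts of a gene and of an antisense partner that overlaps it cannot be told apart, and reads of near-identical copies may have been split between them.

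Total counts per library ran from 87.1 to 130.7 M (1000000 counts), with a median of 105 M, and 13741 to 16388 genes had a count per library. Low values pile up at multiples of 4. Of 183786 values between 1 and 24, 36.8% are multiples of 4, against 25% if values were spread evenly; 25597 values equal 4, against 9686 equal to 3 and 13161 equal to 5. A single sequenced fragment therefore appears to be worth about 4 deposited counts, and the depth behind a value is about 0.25 of what the totals state. The test estimates its spread from the replicates and was repeated on values divided by 4. Reads carry no molecular identifiers, so floors cover counting error only. No library pair within a group was identical: over 120 pairs the lowest chi-squared per gene was 12.06 and the median 29.055.

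Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr with a minimum count of 10) and Benjamini-Hochberg adjustment within each comparison, with an adjusted p of 0.05 as the threshold. An adjusted p of a gene is from this test throughout. Each stage or sex had its own fit of all its libraries, with 14634 genes tested in larvae, 13471 in females and 15847 in males. In adults, groups of 6 and 12 cycles were averaged with equal weight, so that n = 8 per side. In each fit 4 contrasts were tested: fluctuating against constant at the high point, the same at the low point, the high against the low point at constant temperature, and the difference of the treatment effect between the points. In adults the treatment effect at 12 cycles was also tested against that at 6. A fit of the 64 adult libraries (16058 genes) tested males against females, and a fit of all 80 libraries (16306 genes) tested larvae against the mean of the adults. No covariates were used. A gene's error is the standard error (SE) of its log2 fold change; levels are counts per 1000000 (CPM) scaled by TMM factors, as mean ± SD over libraries. Summed levels of lists and of the glue protein genes, and those of Acp36DE beside the larval list, are CPM before scaling.

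Sets of genes were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 8, a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 324 tests (27 lists in the 12 contrasts of the separate fits). Beside it stand camera with the correlation estimated from the data and fry, whose p tests whether the genes of a set move, on balance, one way, and which does not compare the set with other genes. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. The lists, with the members measured in the file, were heat shock proteins and co-chaperones (28), endoplasmic reticulum (ER) chaperones and unfolded protein response (19), Turandot and cold marker genes (10), antimicrobial and immune effectors (43), circadian clock (19), photoreceptor markers (29), neuron markers (19), yolk, vitelline and chorion proteins (29), ovarian germline (28), testis and spermatogenesis (40), male accessory gland and ejaculatory bulb (52), late third-instar and ecdysone-responsive genes (45), larval and pupal cuticle proteins (60), digestive proteases and glycosidases (54), glycolysis, glycogen and trehalose (26), fatty acid and lipid metabolism (41), oxidative phosphorylation (67), cytosolic ribosomal proteins (80), ribosome biogenesis (29), detoxification by P450, GST and UGT enzymes (100), antioxidant enzymes (35), proteasome (34), DNA replication and cell cycle (35), muscle structure (30), hemocyte markers (19), V-ATPase and Na/K-ATPase (31), and markers of sex (12). The symbols Hop, Pdi, BaraA2, Nlf, Trh, palisade, don-juan, FASN3, RpL37a, RpS12, hoip, Cyp6a21, Orc1 and Vha44 matched no gene and were not used here. Most lists of tissue markers hold genes that other tissues of a whole animal also express.

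The comparisons, lists, tests, the rule for named genes and the alternatives were fixed before the data were examined, except for the alternatives and tests named as later choices in the closing section. For each of the 6 comparisons of fluctuating with constant animals, the rule took the 8 higher and 8 lower genes with the largest log2 fold change among those past the threshold that had a mean of at least 5 CPM and no overlap between the libraries of the sides within a cycle number. It also took up to 4 members of each list with the smallest p among those past the threshold. For the other comparisons it took 4 genes each way, with no condition on overlap for interactions. A set of 23 genes was taken in every comparison: Hsp22, Hsp23, Hsp26, Hsp27, Hsp68, Hsp70Aa, Hsp83, DnaJ-1, Hsf, Fst, smp-30, TotA, TotC, per, tim, Clk, vri, Pdp1, cry, Yp1, Acp26Aa, roX1 and Sxl. Not every gene taken is named in the text. No fitted fold is given for a gene with a group at 0. Genes named for being called at both points or in all stages were chosen after their values were seen.

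The steps were tested on simulated counts with 200 changed genes before use. In the larval comparison at the high point (14634 genes), 32.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 81.8% of those changed 4-fold were recovered with 5 false calls. The shares were 80.6%, 92.5% and 97% in females (13471 genes, 10 false calls) and 82.1%, 88.1% and 100% in males (15847 genes, 8 false calls). The alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR (RLE), no filter on low counts, a minimum count of 50, a robust fit, a fit of only the libraries compared, a replicate block, a threshold of 0.01, each library left out in turn, counts divided by 4, 6 or 12 cycles alone, and the male comparisons without 1 library that holds female transcripts.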

Results

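The expression of genes was measured by RNA sequencing in whole larvae, adult females and adult males of Drosophila melanogaster kept at a constant 19 °C or under a cycle between 27 °C and 11 °C with the same mean. There were 16 larval, 32 female and 32 male libraries in 20 groups of 4, defined by stage or sex, regime, the high or low point of the cycle, and in adults 6 or 12 cycles. Total counts (M, 1000000 counts) ran from 94 to 126.2 M in larvae (median 111.85), from 92.9 to 130.7 M in females (median 109.25) and from 87.1 to 122.6 M in males (median 100.05). A single fragment appears to be worth about 4 counts, so the real depth is about 0.25 of these totals. In larvae n is 4 libraries per side, and in adults n is 8, 4 at each cycle number.

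The comparison of fluctuating with constant larvae at the low point asked what animals at the cool end of the cycle express that animals at constant temperature do not. Inducible chaperone genes rose. Hsp70Ab (FBgn0013276, chromosome 3R, 11958535 to 11960909, + strand), which encodes the main heat-inducible chaperone, rose from 6.22 ± 6.45 to 286.5 ± 153.2 CPM (mean ± SD, n = 4, log2 fold change 5.52, SE 0.755, adjusted p = 0.00224). The copies Hsp70Aa, Hsp70Ba, Hsp70Bb, Hsp70Bbb and Hsp70Bc rose by 5.48, 5.11, 5.07, 4.96 and 4.6 on the log2 scale. Reads of these near-identical genes may be shared among them. The co-chaperone DnaJ-1 (3L, 5750029 to 5752189, - strand) rose from 85.2 ± 13.9 to 445 ± 61.0 CPM (log2 fold change 2.39, SE 0.171, adjusted p = 9.48e-06). Hsp83 (3L, 3192969 to 3197059, + strand), the fly Hsp90, rose from 947 ± 57.3 to 2236 ± 187 CPM (1.24, SE 0.0957, adjusted p = 1.32e-05). Hsp68 was higher by 0.91 (adjusted p = 0.0344), a call lost without 7 of the 16 libraries, each left out alone. The small heat shock genes did not pass: the log2 fold changes were 2.96 for Hsp22 (adjusted p = 0.132), 0.79 for Hsp26 (0.0559), 0.21 for Hsp23 (0.748) and 0.08 for Hsp27 (0.887).

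Of the 28 measured heat shock proteins and co-chaperones, 12 rose and 0 fell at the low point (18 and 1 adjusted over the list alone). The list as a whole rose (camera, adjusted p = 2.63e-22, adjusted p = 0.0444 with an estimated correlation). Of 19 hemocyte markers 4 were lower and 0 higher. They were led by He, a surface protein of blood cells (-0.83, SE 0.119, adjusted p = 0.00311), and the phagocytosis receptors NimC1 (-0.61, adjusted p = 0.0123) and eater (-0.67, adjusted p = 0.0237). The call of that list (adjusted p = 3.06e-07) was lost with the correlation estimated (adjusted p = 0.13 with an estimated correlation). PPO3, a phenoloxidase of lamellocytes, fell by 1.55 and the integrin subunit ItgaPS4 by 2.92, both calls lost without 7 of the libraries. The P450 gene Cyp304a1 fell by 1.13 (adjusted p = 0.00166), while the maltase gene Mal-A3 rose by 3.19 (adjusted p = 0.032, lost without 7 libraries) and the metallothionein gene MtnB by 1.01 (adjusted p = 0.014, lost without 1 library). The 25 measured genes of the male accessory gland list rose as a set (adjusted p = 6.77e-18, adjusted p = 0.0493 with an estimated correlation) with 2 of them past the threshold (15 adjusted over the list alone). They lie near the floor: the seminal fluid gene Acp36DE had a mean of 0.225 CPM before scaling in constant and 1.23 in fluctuating larvae. At the same point and 6 cycles it was at 0.389 and 1.46 CPM in females and at 757 and 1280 in males, and at 12 cycles at 0.831 and 0.428 in females and 662 and 876 in males. Whether larvae express these genes or their libraries hold a trace of male transcripts was not tested.

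Further lists shifted at the larval low point with few members past the threshold, and each of these calls was lost with an estimated correlation. Where 2 adjusted p follow a list, the second is the adjusted p with an estimated correlation. Cytosolic ribosomal proteins were lower (adjusted p = 3.89e-08 and 0.878). So were ribosome biogenesis (adjusted p = 2.3e-04 and 0.796), immune effectors (adjusted p = 0.00839 and 0.796), V-ATPase and Na/K-ATPase genes (adjusted p = 0.0432 and 0.924) and late third-instar genes (adjusted p = 0.0443 and 0.582), the last with a median of -0.14 and a mean of 0.07. ER chaperones (adjusted p = 0.00901 and 0.812), the yolk and eggshell list (adjusted p = 0.00139 and 0.381) and the testis list (adjusted p = 8.57e-05 and 0.92) were higher. Sex share was not tested: its marker roX1 ran from 67.9 to 176 CPM before scaling in fluctuating and 81 to 121 in constant low larvae. A library stands apart beside the yolk list: Yp1 was at 4.839 CPM in fluctuating low replicate 3 and at 0.0969 to 0.193 CPM in the other 3 of its group, and at 5.457 CPM in fluctuating high replicate 4. In total 162 of 14634 genes were called at the low point by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 64 higher and 98 lower, of which 29 and 20 changed at least 2-fold. Of the 162 genes 39 kept the call with every library left out in turn. The count fell to 44, 57, 51 and 77 without constant low replicates 1, 2, 3 and 4 and to 82, 85, 59 and 101 without fluctuating low replicates 1, 2, 3 and 4, and was 270 without fluctuating high replicate 4. DESeq2 called 524 and a fit of the compared libraries alone 253.

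**Figure D1:**
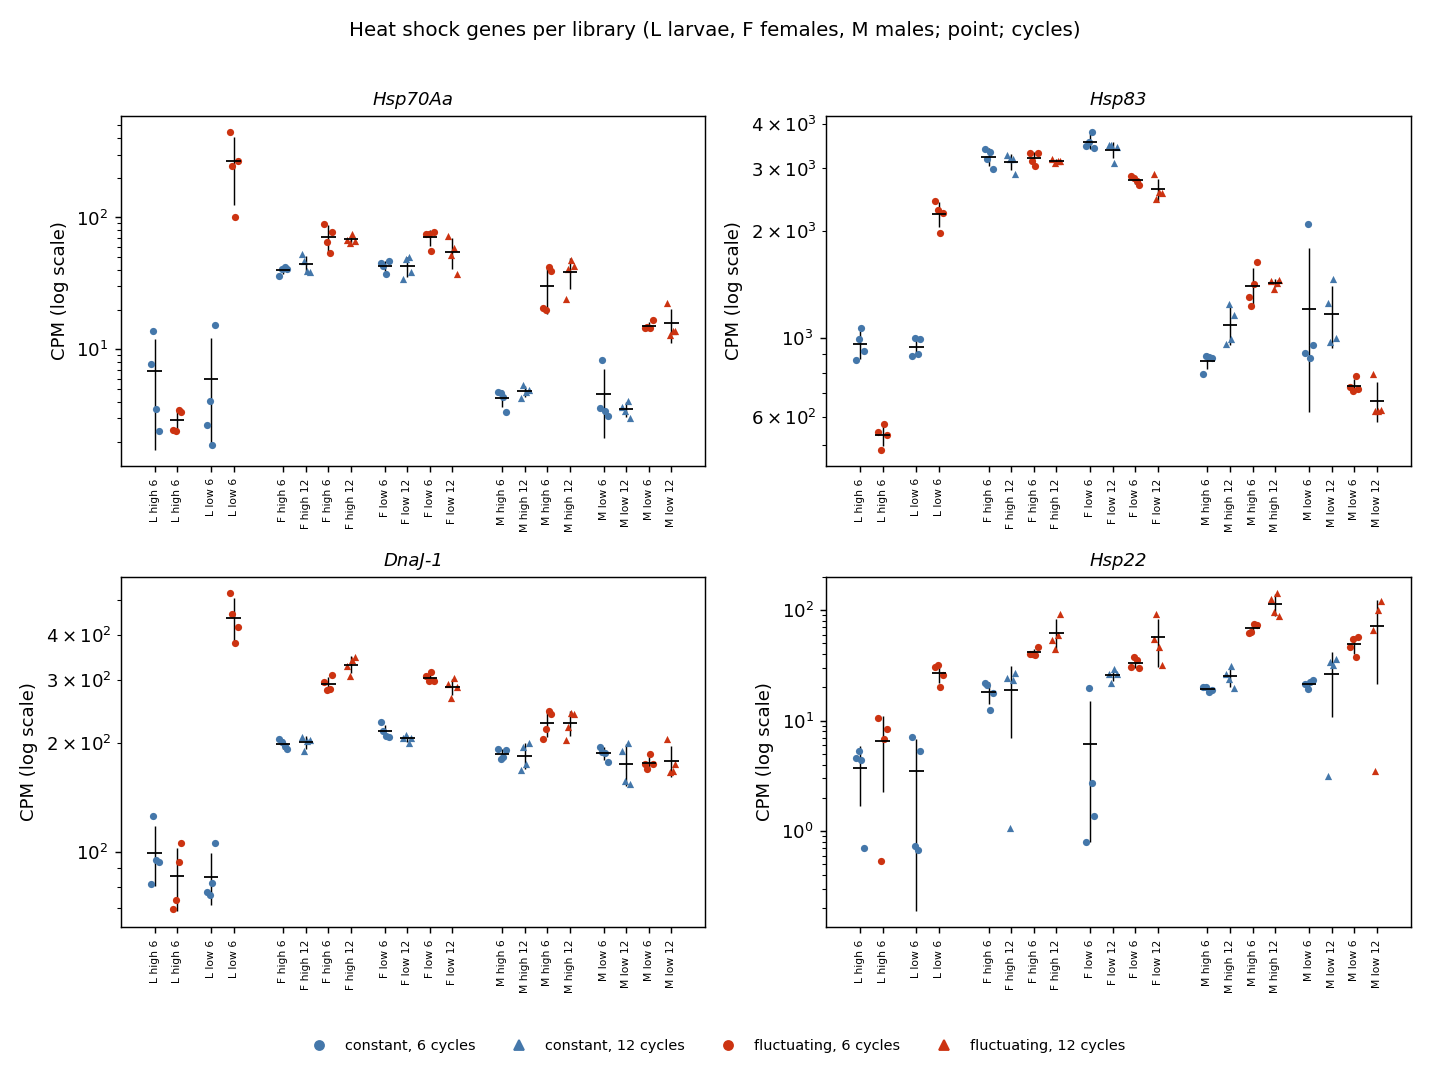
Levels of Hsp70Aa, Hsp83, DnaJ-1 and Hsp22 in CPM on log axes, 1 point per library, for larvae (L), females (F) and males (M) by point and cycle number. Blue is constant and red fluctuating, horizontal bars are group means and vertical lines ± 1 SD (n = 4), drawn down to the lowest library where mean minus SD is 0 or less. The 4 larval libraries of the low point under fluctuation lie at 101.3 to 448.1 CPM for Hsp70Aa, above all 4 constant ones (1.878 to 15.22 CPM).

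At the high point the same comparison asked what larvae at the warm end of the cycle express. Hsp83 went the other way and fell from 963 ± 87.8 to 535 ± 36.1 CPM (-0.85, SE 0.0949, adjusted p = 4.24e-04). Hsp23, a small heat shock gene, rose from 1528 ± 374 to 3032 ± 1229 CPM (0.99, adjusted p = 0.0418), a call lost without 10 of the libraries. Hsp70Aa (-1.24, adjusted p = 0.288) and DnaJ-1 (-0.21, adjusted p = 0.509) did not pass. The salivary glue gene Sgs5bis rose from 1075 ± 142 to 3271 ± 1463 CPM (1.61, adjusted p = 0.00938). The tetraspanin gene Tsp42Ej rose by 1.16 (adjusted p = 0.00498), and the antisense RNA asRNA:CR45210 rose by 2.92 (SE 0.273, adjusted p = 1.71e-04). The glutathione transferase genes GstD2, GstD5 and GstD10 fell by 4.10, 3.58 and 1.73, and GstD2 went from 56.1 ± 66.4 to 3.26 ± 2.28 CPM. Npc2h, of the sterol-binding NPC2 family, fell by 3.77 (SE 0.396, adjusted p = 2.48e-04). The antifungal peptide gene Drs fell by 1.84 (adjusted p = 0.0177, lost without 1 library), the lysozyme gene LysP by 1.12 (adjusted p = 0.00938) and PPO3 by 1.61 (adjusted p = 0.0122).

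Among the lists at the larval high point, detoxification genes fell (0 higher and 17 lower of 100, 31 lower adjusted over the list alone, adjusted p = 5.71e-13). So did cuticle proteins (1 and 9 of 53, 1 and 21 over the list alone, adjusted p = 2.21e-10), with Lcp65Ae lower by 3.52 log2 units and Lcp65Ad higher by 2.12. Both calls were lost with the correlation estimated (adjusted p = 0.686 for detoxification and 0.482 for cuticle). Of the 26 genes of glycolysis, glycogen and trehalose 0 were higher and 4 lower (1 and 17 over the list alone, adjusted p = 5.26e-08, adjusted p = 0.682 with an estimated correlation). Among them lactate dehydrogenase Ldh went from 285 ± 82.8 to 107 ± 49.4 CPM and phosphofructokinase Pfk from 225 ± 47.9 to 105 ± 43.6 CPM, both calls lost without 6 libraries. Muscle genes (1 and 1 of 30, 1 and 15 over the list alone, adjusted p = 2.95e-08 and 0.686 with an estimated correlation) and digestive enzymes (0 and 4 of 54, adjusted p = 4.6e-07 and 0.812) were lower as sets. So were immune effectors (1 and 5 of 41, adjusted p = 4.58e-06 and 0.526) and ER chaperones (0 and 4 of 19, adjusted p = 7.21e-05 and 0.686). Oxidative phosphorylation (0 and 0 of 67, adjusted p = 5.18e-09 and 0.812) and lipid metabolism (0 and 1 of 40, adjusted p = 0.00726 and 0.812) were lower as well, the second p of each again with an estimated correlation. The ER genes include the chaperones Gp93 (-0.51) and Hsc70-3 (-0.43) and the ubiquitin ligase gene sip3 (-0.31), and the digestive genes include the maltase gene Mal-B2 (-1.01). Proteasome (3 and 0 of 34, 16 higher over the list alone, adjusted p = 1.15e-08 and 0.796) and ribosome biogenesis genes (4 and 0 of 29, adjusted p = 7.54e-06 and 0.695) were higher as sets. DNA replication genes were too (1 and 0 of 35, adjusted p = 9.51e-04 and adjusted p = 0.605). The proteasome subunit gene Rpn8 rose by 0.41 (adjusted p = 0.0294).

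The other lists were not called at the larval high point: heat shock (adjusted p = 0.934, median 0.07, mean -0.13), Turandot and cold markers (0.085), clock (0.711, median 0.01, mean -0.10), photoreceptor (0.763), neuron (0.55), yolk (0.466), germline (0.673) and testis (0.684). Nor were accessory gland (0.729, tested as lower with a median of 0.52), late third-instar (0.68, median 0.07, mean -0.26), ribosomal proteins (0.98), antioxidant (0.0616), hemocyte (0.0613), V-ATPase (0.535) and sex markers (0.982). Larval libraries of a group differ along the same genes. Constant high libraries had 26138 to 43801 CPM of cuticle, 30442 to 43407 of digestive and 18622 to 32909 of muscle genes, replicate 3 lowest. In constant low larvae cuticle and muscle genes reached only 24642 and 17597 CPM, so falls may lie in the constant high group. A total of 639 of 14634 genes were called (308 higher, 331 lower, 35 and 173 at least 2-fold), and 135 kept the call with every library left out in turn. The count was 201, 190, 1137 and 230 without constant high replicates 1, 2, 3 and 4, and 422, 420 and 407 without constant low replicates 1, 2 and 3. It was 1162, 167, 321 and 244 without fluctuating high replicates 1, 2, 3 and 4. DESeq2 called 1603 (754 higher, 849 lower) and a fit of the compared libraries alone 22 (5 and 17).

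At constant temperature the high and low points differ by design only in the time of sampling. In larvae it was led by the regucalcin relative smp-30 (45.9 ± 22.8 against 6.08 ± 2.46 CPM), the cuticle genes Cpr67Fa2 (3.77) and Lcp65Ae (3.13), GstD2 (3.74) and Mal-A3 (3.38), all higher at the high point. Atet (-0.66) and the neurotrophin gene NT1 (-0.70) were lower there (each adjusted p = 0.0494). Sets were higher for cuticle proteins (4 and 0 of 53, 34 over the list alone, adjusted p = 4.18e-16, adjusted p = 0.185 with an estimated correlation) and oxidative phosphorylation (0 and 0, 53 over the list alone, adjusted p = 1.43e-23 and adjusted p = 0.582). They were also higher for digestive enzymes (2 and 0, adjusted p = 9.92e-15 and 0.68) and muscle (0 and 0, adjusted p = 1.15e-08 and 0.682). In all 61 genes were called (51 higher, 10 lower), and this count rests on single libraries. It was 0 without constant high replicate 1, 2 or 4, without constant low replicate 1, 3 or 4, and without fluctuating low replicate 2 or 4 or fluctuating high replicate 2. It was 2 without constant low replicate 2, 1322 without constant high replicate 3 and 542, 450 and 328 without fluctuating high replicates 1, 3 and 4. It was 727 and 31 without fluctuating low replicates 1 and 3. In edgeR 0 genes kept the call in every such fit, while DESeq2 called 1407. With no filter on low counts edgeR called 0 genes and with a robust fit 1, against 3054 genes with an unadjusted p under 0.05 in the fit reported. A fit of the compared libraries alone called 753.

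The difference between the larval treatment effects at the points was called for 247 genes (116 of them lower and the others higher at the high point relative to the low one). Hsp70Ab (-6.76, adjusted p = 0.00418), Hsp70Aa (-6.71), DnaJ-1 (-2.60, adjusted p = 6.97e-05) and Hsp83 (-2.09, adjusted p = 2.21e-06) kept the call with each library left out. Of the heat shock list 0 were higher and 10 lower (2 and 14 over the list alone, adjusted p = 6.58e-10, adjusted p = 0.105 with an estimated correlation). Of the ER list 0 were higher and 4 lower (1 and 9 over the list alone, adjusted p = 3.57e-06 and adjusted p = 0.624). Ribosome biogenesis was higher as a set (1 and 0, 11 over the list alone, adjusted p = 1.15e-08 and adjusted p = 0.582). The count was 88, 91, 640 and 126 without constant high replicates 1 to 4, and 96, 90, 75 and 113 without constant low replicates 1 to 4. It was 617 and 75 without fluctuating high replicates 1 and 2, and 113, 141 and 140 without fluctuating low replicates 1, 2 and 3. DESeq2 called 1048.

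In females at the high point, chaperone genes rose, and per, vri and Desat1 fell. Hsp68 went from 3.60 ± 0.661 to 12.8 ± 2.61 CPM (n = 8, log2 fold change 1.83, SE 0.141, adjusted p = 3.48e-10) and Hsp70Bb from 2.31 ± 0.507 to 9.58 ± 3.30 CPM (2.05, SE 0.202, adjusted p = 2.54e-08). The small heat shock gene l(2)efl rose from 24.8 ± 3.94 to 52.0 ± 4.44 CPM (1.08) and DnaJ-1 from 200 ± 6.59 to 311 ± 25 CPM (0.64, SE 0.0306, adjusted p = 4.28e-14). Hsp83 differed by -0.00 (adjusted p = 0.963). The clock gene per (X, 2685580 to 2692780, + strand) fell from 29.9 ± 9.12 to 12.0 ± 0.797 CPM (-1.27, SE 0.0892, adjusted p = 6.49e-11). The clock gene vri (2L, 5288944 to 5311223) fell from 57.7 ± 10.9 to 34.2 ± 3.02 CPM (-0.74, adjusted p = 2.97e-08). Desat1, the fatty acid desaturase, fell from 2118 ± 332 to 1245 ± 126 CPM (-0.77, adjusted p = 4.18e-06). Trehalose synthase Tps1 fell by 0.57, the gluconeogenic Pepck1 by 1.58 and Fst (Frost), known for its rise after cold, by 1.52 (24.6 ± 5.48 to 8.62 ± 1.96 CPM, adjusted p = 4.13e-06). Pepck1 was not called with 12 cycles alone (adjusted p = 0.557). The mannosidase gene LManIII (2.06, adjusted p = 6.35e-05) and the storage protein gene Lsp1beta (2.19) rose. The antimicrobial peptide genes Dro and DptB rose by 4.22 (adjusted p = 6.15e-04) and 3.69 (adjusted p = 8.59e-04), while the immune list as a whole was not called. With 1.27 ± 0.699 against 24 ± 40.6 CPM for Dro the fluctuating libraries spread widely.

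By list, 17 of 28 heat shock genes rose and 1 fell (the same adjusted over the list alone, adjusted p = 1.41e-09, adjusted p = 0.0388 with an estimated correlation). Of 29 yolk, vitelline and chorion genes 15 rose and 0 fell (17 over the list alone, adjusted p = 8.86e-06 and adjusted p = 0.796 with an estimated correlation), among them the vitelline membrane genes Vm34Ca (1.64, 193 ± 96.5 to 612 ± 252 CPM) and Vm26Aa (1.12). Of 28 ovarian germline genes 6 rose and 4 fell, and the list was not called (adjusted p = 0.852). Digestive enzymes rose (19 and 2 of 54, 22 and 2 over the list alone, adjusted p = 0.00162 and 0.812). So did ER chaperones (9 and 1, 11 and 1 over the list alone, adjusted p = 0.00967 and adjusted p = 0.566), led by Grp170 (0.32). Lower as sets were glycolysis, glycogen and trehalose (0 and 13 of 26, 1 and 14 over the list alone, adjusted p = 1.78e-04 and adjusted p = 0.785) and ribosomal proteins (1 and 28 of 80, 1 and 29 over the list alone, adjusted p = 2.23e-04 and adjusted p = 0.893) with RpL11 at -0.30 and RpS6 at -0.29. RpL11 (adjusted p = 0.536) and RpS6 (adjusted p = 0.401) were not called with 12 cycles alone. Neuron markers (0 and 7 of 19, adjusted p = 0.0104 and 0.812) with ChAT, the acetylcholine synthase, at -0.51, and clock genes (2 and 6 of 19, 2 and 7 over the list alone, adjusted p = 0.0145 and 0.582) were lower too. So were muscle (2 and 12 of 30, adjusted p = 0.0241 and 0.934), detoxification (8 and 30 of 100, adjusted p = 0.0311 and 0.92) and lipid metabolism (5 and 13 of 41, adjusted p = 0.0418 and 0.812), each second p with an estimated correlation. Late third-instar genes were lower (5 and 10 of 32, adjusted p = 2.85e-05 and adjusted p = 0.105 with an estimated correlation). Beside this list stands a trace of larval transcripts: summed glue protein genes (Sgs) reached 6.33 to 19.1 CPM in the 8 constant adult libraries of the high point at 6 cycles, against 0 to 1.44 in the other 56 adult libraries.

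The lists not called in females at the high point were Turandot (adjusted p = 0.0755), immune (0.752, 10 higher and 6 lower), photoreceptor (0.0941), testis (0.716), accessory gland (0.963), cuticle (0.279), oxidative phosphorylation (0.281, 2 and 12) and ribosome biogenesis (0.248, 11 and 6). Nor were antioxidant (0.991, 6 and 7, tested as higher with a median of -0.01), proteasome (0.92, 3 and 4, tested as higher with a median of -0.01), DNA replication (0.0533, 6 and 0), hemocyte (0.158), V-ATPase (0.933, 8 and 7) or sex markers (0.108, 3 and 0) called. A total of 4128 of 13471 genes were called, 2070 higher and 2058 lower, of which 200 and 116 changed at least 2-fold. With the groups of 12 cycles alone 1612 were called, and 4111 with those of 6 cycles alone.

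At the low point in females, per rose and vri fell. The per gene went from 37.9 ± 16.5 to 68.1 ± 12.5 CPM (0.93, adjusted p = 2.45e-08). The rise was 0.19 with 6 cycles alone (adjusted p = 0.293) and 1.67 with 12 cycles alone. In contrast vri fell from 50.8 ± 14.4 to 18 ± 1.95 CPM (-1.46, SE 0.0747, adjusted p = 1.95e-13) and the light receptor gene cry by 0.44 (adjusted p = 0.00715). Kr-h1, a juvenile hormone-responsive transcription factor, rose from 20.1 ± 2.56 to 51.2 ± 11 CPM (1.35, SE 0.159, adjusted p = 8.94e-07), Ldh rose by 0.93 (adjusted p = 6.68e-05) and the elongase gene eloF by 0.87. Hsp83 fell from 3476 ± 191 to 2700 ± 157 CPM (-0.37, SE 0.0362, adjusted p = 5.27e-08), whereas DnaJ-1 (0.49, adjusted p = 1.8e-11), Hsp68 (log2 fold change 1, adjusted p = 7.38e-06) and Hsp70Aa (0.55, adjusted p = 8.37e-04) rose. With 12 cycles alone Hsp70Aa (adjusted p = 0.127) and cry (0.235) were not called. The vitamin transporter gene Smvt fell by 1.15 and the hemocyte gene Hml by 0.59 (adjusted p = 7.82e-05). CG18609 rose by 1.08 at the low point, against -1.41 at the high point.

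Of 80 ribosomal protein genes 39 were higher and 3 lower at the female low point (42 and 4 adjusted over the list alone, adjusted p = 2.84e-09, adjusted p = 0.723 with an estimated correlation), with RpL35A at 0.27. Oxidative phosphorylation rose (25 and 6 of 67, 28 and 8 over the list alone, adjusted p = 0.00219 and 0.92), with COX8, a subunit of cytochrome oxidase, at 0.33. ER chaperones fell (2 and 11 of 19, 3 and 13 over the list alone, adjusted p = 1.61e-05 and 0.0826). Gp93 was at -0.37, Calr at -0.31 and Cnx99A at -0.28 (adjusted p = 2.37e-09), although the stress sensor gene Ire1 rose by 0.36. Hemocyte markers fell (0 and 6 of 19, 0 and 9 over the list alone, adjusted p = 8.36e-04 and 0.682). Ribosome biogenesis (3 and 11 of 29, adjusted p = 0.00521 and 0.812) and proteasome genes (2 and 11 of 34, adjusted p = 0.0348 and 0.938) fell as sets too, each second p with an estimated correlation. The heat shock list split into 9 higher and 6 lower and was not called (adjusted p = 0.567). A total of 3082 genes were called (1541 higher, 1541 lower, 169 and 56 at least 2-fold). With 12 cycles alone 1802 were called.

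Between the points at constant temperature, females differed in cry, Clk and tim, while the clock list was not called (5 higher and 6 lower of 19, adjusted p = 0.89). The cry gene stood at 76.0 ± 12.8 CPM at the high and 26.5 ± 4.40 CPM at the low point (1.52, SE 0.119, adjusted p = 1.77e-09). Clk was higher by 0.77 (adjusted p = 4.36e-07), tim was lower (85.5 ± 15.3 against 153 ± 24.4 CPM, -0.84, adjusted p = 7.43e-07), and Fst was higher by 1.25. CG17560 (1.57) and CG3739 (-3, 9.06 ± 5.16 against 72.9 ± 25.4 CPM) had large differences. Ribosomal proteins (71 and 0 of 80, 75 over the list alone, adjusted p = 6.15e-34, adjusted p = 0.127 with an estimated correlation) were higher at the high point. Oxidative phosphorylation (43 and 0, 54 over the list alone, adjusted p = 5.67e-15 and 0.541) and muscle (20 and 0 of 30, adjusted p = 1.94e-08 and 0.682) were higher there too. DNA replication genes were lower (0 and 20 of 35, 0 and 24 over the list alone, adjusted p = 8.01e-10 and 0.682). Late third-instar (7 and 3, adjusted p = 2.7e-06 and 0.0826) and cuticle genes (7 and 1, adjusted p = 0.00521 and 0.175) were higher at the high point, where the Sgs transcripts of 6 cycles lie. In all 2846 genes were called (1465 higher, 1381 lower), and 604 with 12 cycles alone.

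The female treatment effect differed between the points for 2692 genes (1318 higher, 1374 lower at the high point). The clock gene per (-2.20, adjusted p = 3.07e-12) and Fst (-2.36, adjusted p = 1.55e-06) were lower at the high point relative to the low, and vri (0.72), Hsp68 (0.83) and Hsp83 (0.36, adjusted p = 1.1e-05) were higher. DptA was at 5.84 (adjusted p = 0.00416) and Mtk at 3.97, while the immune list was not called (10 higher and 1 lower of 40, adjusted p = 0.318). CG10570 (2L, 18808694 to 18811252, counted together with CG42502 at the same coordinates) was at -5.72 (adjusted p = 1.18e-06). Hsp68 was at 0.50 with 6 cycles alone (adjusted p = 0.324). With either cycle number alone DptA (adjusted p = 0.0637 and 0.0865) and Mtk (0.0813 and 0.0997) were not called. The heat shock list (14 and 2 of 28, 16 and 2 over the list alone, adjusted p = 1.95e-07, adjusted p = 0.0493 with an estimated correlation) was higher at the high point. So was the ER list (12 and 1 of 19, adjusted p = 2.59e-07 and adjusted p = 0.051), and ribosomal proteins were lower (0 and 44 of 80, 0 and 56 over the list alone, adjusted p = 5.87e-16 and adjusted p = 0.582). Digestive enzymes were higher (14 and 0, 17 over the list alone, adjusted p = 1.35e-04 and 0.714). With 6 or 12 cycles alone 871 and 1343 genes were called.

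**Figure D2:**
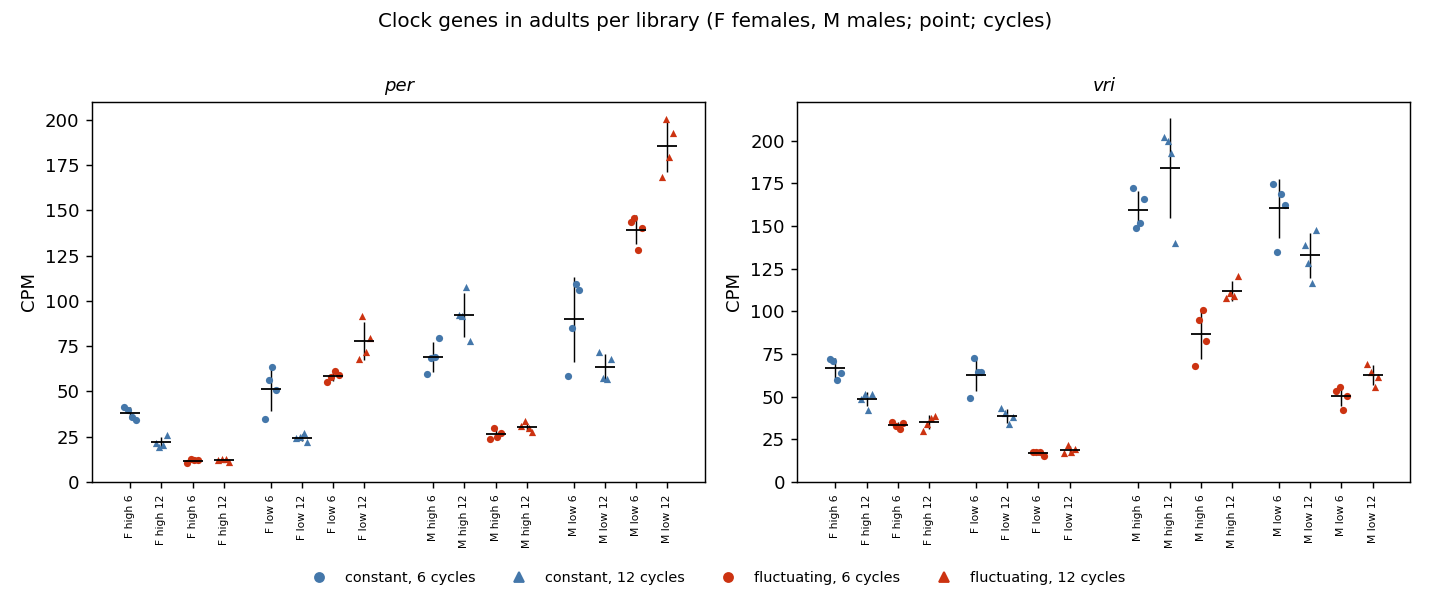
Levels of per and vri in CPM in each adult library for females (F) and males (M) by point and cycle number. Blue is constant and red fluctuating, horizontal bars are means and vertical lines ± 1 SD (n = 4). In fluctuating males per has a mean of 28.4 CPM at the high and 162 CPM at the low point (n = 8), against 80.7 and 76.7 CPM at constant temperature.

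In males at the high point, Hsp70Aa, Lsp2 and apolpp rose, and per fell. Hsp70Aa (3R, 11954163 to 11956544, - strand) went from 4.55 ± 0.586 to 34.6 ± 11.1 CPM (2.92, SE 0.199, adjusted p = 2.85e-11). Hsp22 went from 22.3 ± 4.58 to 91.2 ± 30 CPM (log2 fold change 2, adjusted p = 2.65e-04, its exons overlap those of CG4456 on the same strand) and Hsp83 from 978 ± 153 to 1413 ± 119 CPM (0.54, adjusted p = 0.0018). The larval serum protein gene Lsp2 rose from 307 ± 282 to 1148 ± 575 CPM (2.23, adjusted p = 3.9e-04) and the lipophorin gene apolpp from 1853 ± 247 to 4091 ± 920 CPM (1.14, SE 0.138, adjusted p = 5.05e-07). The per gene fell from 80.7 ± 15.7 to 28.4 ± 3.25 CPM (-1.50, SE 0.0968, adjusted p = 1.57e-11), vri from 172 ± 24.2 to 99.4 ± 17 CPM (-0.80) and the clock repressor gene cwo by 0.90. The sugar-responsive factors sug (-1.55) and cbt (-1.05), the TGF-beta ligand gene daw (-1.15), malic enzyme Men (-0.71) and Desat1 (4550 ± 1009 to 2862 ± 508 CPM, -0.65) fell. The immune peptide genes BomS2 and BaraA1 fell by 0.83 and 0.95. BomS2 was at -0.10 with 12 cycles alone (adjusted p = 0.837), and with 6 cycles alone sug was at -0.55 (adjusted p = 0.464). The dosage compensation RNAs roX1 (0.36, adjusted p = 0.00156) and roX2 (0.89) and the seminal fluid gene Acp53C14a (0.69) rose.

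Of the heat shock list 18 of 28 genes rose and 3 fell in males at the high point (the same adjusted over the list alone, adjusted p = 2.27e-08, adjusted p = 0.0819 with an estimated correlation). Accessory gland genes rose (26 and 3 of 52, 27 and 3 over the list alone, adjusted p = 1.23e-05 and adjusted p = 0.812). So did ribosomal proteins (34 and 3 of 80, 35 and 3 over the list alone, adjusted p = 1.49e-04 and 0.934). Also higher were oxidative phosphorylation (32 and 9 of 67, 34 and 9 over the list alone, adjusted p = 6.02e-04 and adjusted p = 0.924) and sex markers (3 and 0 of 12, adjusted p = 0.0303 and adjusted p = 0.482). Glycolysis, glycogen and trehalose genes fell (2 and 9 of 26, 2 and 10 over the list alone, adjusted p = 0.0025 and adjusted p = 0.723). Lower too were lipid metabolism (2 and 14 of 41, adjusted p = 0.0153 and adjusted p = 0.686), clock genes (3 and 7 of 19, adjusted p = 0.0105 and adjusted p = 0.624) and immune effectors (1 and 7, adjusted p = 0.0451 and adjusted p = 0.92). The immune call was lost without replicate 2 of constant males at the low point and 6 cycles (1 and 8, adjusted p = 0.0721), and the sex markers then had 6 higher and 0 lower. Late third-instar genes (3 and 13 of 34, 3 and 14 over the list alone, adjusted p = 6.95e-05 and adjusted p = 0.127) and cuticle genes (3 and 9 of 50, adjusted p = 0.0296 and adjusted p = 0.0975) were lower. The Sgs transcripts of constant animals at the high point and 6 cycles lie on the side they are compared with. In each pair of p the second is with an estimated correlation. Not called were ER chaperones (adjusted p = 0.784, 5 and 2, tested as higher with a median of -0.02), Turandot (0.566), photoreceptor (0.122), testis (0.527, 6 and 11), antioxidant (0.278), V-ATPase (0.377) and hemocyte genes (0.445). A total of 5052 of 15847 genes were called (2525 higher, 2527 lower, 214 and 100 at least 2-fold), and 2762 and 2773 with 6 or 12 cycles alone.

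At the low point in males, per rose from 76.7 ± 21.4 to 162 ± 26.8 CPM (1.09, SE 0.0955, adjusted p = 3.83e-09). Conversely vri fell from 147 ± 20.6 to 56.6 ± 8.52 CPM (-1.38, SE 0.0839, adjusted p = 7.2e-12), cry from 94.1 ± 13.1 to 61.5 ± 9.54 CPM (-0.62) and cbt from 96.8 ± 36.6 to 29.0 ± 1.67 CPM (-1.74, adjusted p = 9.92e-07). Hsp70Aa rose from 4.07 ± 1.74 to 15.4 ± 3.07 CPM (1.94, adjusted p = 2.98e-08), whereas Hsp83 fell by 0.77 (SE 0.129, adjusted p = 6.39e-05) and Hsc70-4, a constitutive Hsp70 gene, by 0.67. DnaJ-1 differed by -0.03 (adjusted p = 0.76). CG14893 rose by 3.86 (SE 0.24, adjusted p = 7.7e-12). The Turandot stress genes TotM (1.75, adjusted p = 0.00495) and TotC (1.68, adjusted p = 0.00488) rose with a wide spread (60 ± 114 CPM for TotC in fluctuating males). These were at 0.36 (adjusted p = 0.826) and 0.43 (adjusted p = 0.778) with 12 cycles alone. The seminal fluid genes Acp76A (1.5) and Acp36DE (713 ± 138 to 1082 ± 263 CPM, 0.59, adjusted p = 0.0013) and Ldh (0.81, adjusted p = 4.09e-09) rose, and the alkaline phosphatase genes Alp9 and Alp10 fell by 1.60 and 1.67.

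A single library stands apart here. Replicate 2 of constant males at the low point and 6 cycles had 4635 CPM of the yolk protein gene Yp1 (X, 10053811 to 10055498), at which the other male libraries had 0.206 to 64.7 CPM. It moves with the yolk, cell cycle and ribosome biogenesis lists. With it 0 of 29 yolk and eggshell genes were higher and 20 lower in males at the low point (25 lower adjusted over the list alone, adjusted p = 0.278), and without it 1 and 0, with the list then called higher (median 0.62, adjusted p = 0.031). DNA replication genes were 0 higher and 22 lower of 35 (0 and 25 over the list alone, adjusted p = 0.0011 and 0.92 with an estimated correlation), and 3 and 8 without it (adjusted p = 0.107). Ribosome biogenesis genes fell with it (0 and 26 of 29, 0 and 27 over the list alone, adjusted p = 5.55e-08 and 0.785) and without it (0 and 21, adjusted p = 7.53e-10). Nop56, a nucleolar protein gene, was at -1.09 with and -0.66 without it. Ribosomal proteins rose (16 and 0 of 80, adjusted p = 5.89e-04 and 0.938 with an estimated correlation, 45 and 0 without the library). Yp1, Yp2, dec, Vml, yellow-g, ndl, nanos, swa, TotX, PGRP-SC1a and Hsp23 lost their calls without it. Hsp26 was not called with it (-0.06, adjusted p = 0.772) and was higher without it (0.18, adjusted p = 0.0384). RnrS, a subunit of ribonucleotide reductase, went from -0.88 to -0.35.

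ER chaperones fell at the male low point (1 and 12 of 19, adjusted p = 2.94e-06, adjusted p = 0.44 with an estimated correlation), with CaBP1 at -0.77, Sil1 at -0.69 and Herp at -0.48 (adjusted p = 1.46e-09). Accessory gland genes rose (24 and 0 of 52, adjusted p = 4.78e-08 and 0.762). V-ATPase and ion transport genes fell (2 and 13 of 31, 2 and 16 over the list alone, adjusted p = 0.00681 and 0.812). Turandot genes rose (4 and 0 of 9, 5 over the list alone, adjusted p = 0.0425 and 0.624), a call lost without the library with yolk transcripts (3 and 0, adjusted p = 0.0861). The sex markers were called higher (5 and 4 of 12, adjusted p = 0.0494 and 0.582) with a median of 0.18 and a mean of -0.99, each second p with an estimated correlation. Without that library the sex markers were 5 higher and 0 lower (median 0.465, adjusted p = 0.00453). The heat shock list was not called (adjusted p = 0.991, 7 higher and 8 lower, tested as higher with a median of -0.00). Nor were testis (0.0617, 8 and 2), clock (0.136, 2 and 6) and antioxidant genes (0.811, 7 and 5, tested as higher with a median of -0.03) called. A total of 4829 genes were called (2015 higher, 2814 lower, 231 and 169 at least 2-fold). The number was 4348 without the library that holds yolk protein transcripts (1959 and 2389), of which 3904 were among the former, and 1473 with 12 cycles alone (734 and 739).

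**Figure D3:**
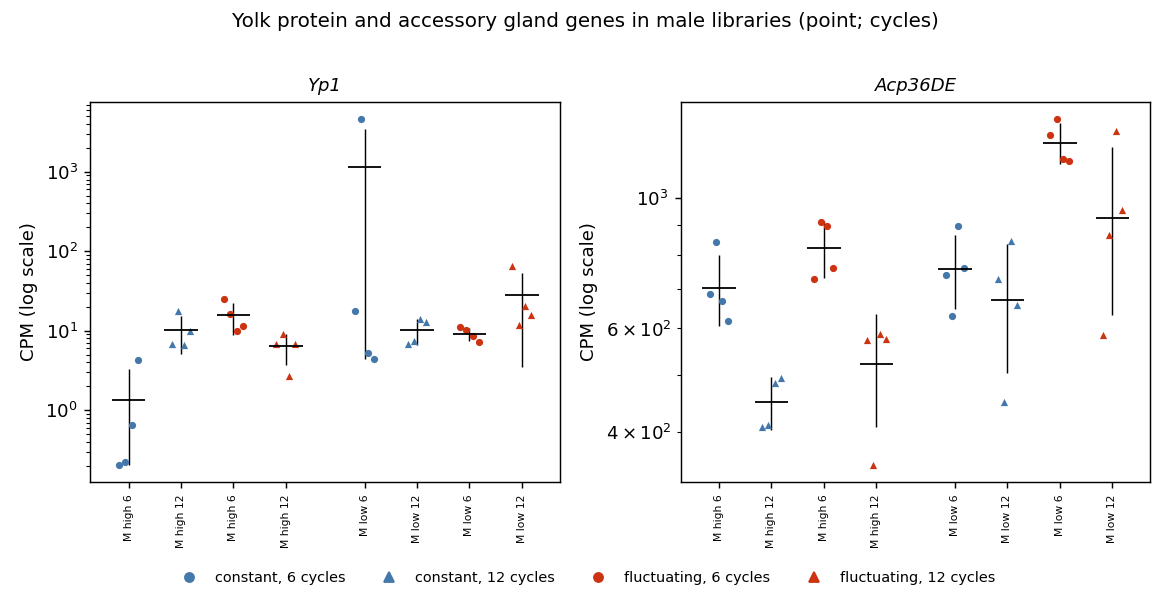
Levels of the yolk protein gene Yp1 and the seminal fluid gene Acp36DE in CPM on log axes in each male library by point and cycle number. Blue is constant and red fluctuating, horizontal bars are means and vertical lines ± 1 SD (n = 4), drawn down to the lowest library where mean minus SD is 0 or less. Replicate 2 of constant males at the low point and 6 cycles lies at 4635 CPM of Yp1, above every other male library.

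Between the points at constant temperature, males showed cry at 261 ± 37.0 against 94.1 ± 13.1 CPM (1.46, SE 0.0624, adjusted p = 1.37e-15). They had tim at 247 ± 75.4 against 496 ± 90 CPM (-1.03, adjusted p = 1.27e-08) and CG3739 at 58.9 ± 11.5 against 513 ± 225 CPM (-3.08). Cyp4d21 (-1.71) and Acsx3 (-1.51) were lower at the high point and smp-30 (0.76) higher. The fat body gene Fbp1 was higher by 4.42 (adjusted p = 2.31e-04), at 16.2 ± 18.8 against 0.124 ± 0.13 CPM, in the groups where the Sgs transcripts lie. Late third-instar genes were higher (10 and 1 of 34, adjusted p = 4.35e-06, adjusted p = 0.0826 with an estimated correlation). So were cuticle (5 and 1, adjusted p = 0.00609 and 0.051) and testis genes (7 and 1, adjusted p = 5.37e-05 and 0.812). Oxidative phosphorylation (0 and 14, adjusted p = 3.89e-08 and 0.812) and ribosomal proteins (0 and 12, adjusted p = 4.86e-07 and 0.899) were lower. Ribosome biogenesis (0 and 17, adjusted p = 1.67e-09 and 0.695) and yolk genes (0 and 25, adjusted p = 1.54e-05 and 0.832) were lower too. Without the library with yolk transcripts the yolk list had 0 higher and 1 lower (adjusted p = 0.0324), ribosomal proteins 1 and 4 (adjusted p = 0.0128) and testis genes 3 and 1 (adjusted p = 0.0235), and Yp1 was at -1.39 (adjusted p = 0.0832, against 0.00191 with it). In all 1527 genes were called (626 higher, 901 lower), 1190 without that library, 667 in a fit of the compared libraries alone and 795 with 6 cycles alone (257 and 538). Fbp1 was not called with 12 cycles alone (adjusted p = 0.488).

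In males the treatment effect differed between the points for 3647 genes (2212 higher, 1435 lower at the high point). The clock gene per (-2.58, adjusted p = 1.62e-13), Fst (-1.57), CG14893 (-3.54) and CG10570 (-4.72) were lower at the high point relative to the low. Higher were Hsp83 (1.31, adjusted p = 4.73e-06), Hsp70Aa (0.99, adjusted p = 0.0068), vri (0.58) and DnaJ-1 (0.32). The heat shock list (16 and 1 of 28, 18 and 2 over the list alone, adjusted p = 1.57e-07, adjusted p = 0.0826 with an estimated correlation) was higher. ER chaperones (12 and 1, adjusted p = 5.79e-05 and 0.582) and ribosome biogenesis (16 and 0, 20 over the list alone, adjusted p = 5.53e-06 and 0.812) were higher as well. Immune effectors (0 and 8, adjusted p = 0.00657 and 0.812) and late third-instar genes (1 and 12, adjusted p = 3.07e-06 and 0.0826) were lower. Beside the latter, the mean Sgs sum was 14.5 CPM in constant males at the high point and 6 cycles and at most 0.555 in the other male groups. Without the library with yolk transcripts 3752 genes were called, Hsp83 was at 1.09, and Yp1, Yp2, Vm34Ca and Cp38 lost their calls. With 6 cycles alone 2191 genes were called (1599 higher, 592 lower) and with 12 cycles alone 2315 (1109 and 1206). Fst was at -0.71 with 12 cycles alone (adjusted p = 0.62), where CG10570 (0.151), Hsp70Aa (0.136), vri (0.144) and DnaJ-1 (0.126) were not called either.

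**Figure D4:**
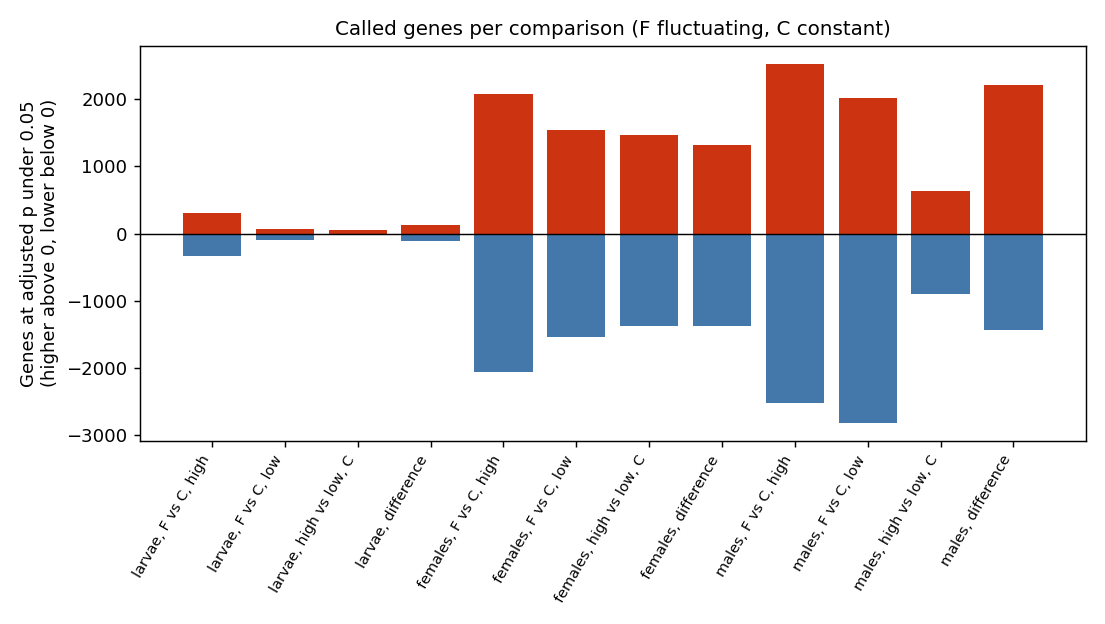
Number of genes at an adjusted p under 0.05 in the 12 comparisons of regime and point within a stage or sex, higher genes above 0 and lower genes below 0 (F fluctuating, C constant). Comparisons of 12 against 6 cycles are not drawn. The counts drawn run from 61 in larvae between the points at constant temperature to 5052 in males at the high point.

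The adult treatment effect at 12 cycles was tested against that at 6. Flies of 12 cycles were also older and of other replicates, so cycle number cannot be told from age or batch. In females at the low point per (1.48, adjusted p = 3.53e-05), vri (0.84, adjusted p = 4.08e-04), tim (0.62) and Fst (1.75) had a more positive treatment effect after 12 cycles. TotA had a more negative one (-2.98, adjusted p = 0.0115). At the high point the effect on per (0.83, adjusted p = 0.00528), vri (0.54, adjusted p = 0.0252) and Pepck1 (2.22, adjusted p = 0.0287) was more positive. In constant females low-point vri fell from 62.67 to 38.93 CPM and per from 51.31 to 24.49, against 17.03 to 18.91 and 58.38 to 77.71 under fluctuation. At the high point vri went from 66.9 to 48.58 CPM and per from 38.01 to 21.86, against 33.31 to 35.04 and 11.8 to 12.09. Females had 2825 genes with a different effect at the low point (1410 higher, 1415 lower). They had 1158 at the high point (491 higher, 667 lower), where constant 6-cycle females held Sgs transcripts. The latter count was 628 without constant high 12-cycle replicate 6 and 590 without constant high 6-cycle replicate 2. It was 701 and 742 without fluctuating high 12-cycle replicates 6 and 7 and 567 without fluctuating high 6-cycle replicate 4. Males had 9 at the high point, all higher, and constant 6-cycle males there held Sgs transcripts. Among the 9 was ImpL2, an insulin-binding protein gene (1.46, adjusted p = 0.00412). The count was 5 without constant high 6-cycle replicate 3 or fluctuating high 6-cycle replicate 4, and DESeq2 called 16. At the low point males had 752 (549 higher, 203 lower), among them the lipid droplet gene Lsd-1 (-2.89, adjusted p = 0.00567), per (0.91, adjusted p = 0.00799) and vri (0.59, adjusted p = 0.0375). That count was 363 and 453 without constant low 12-cycle replicates 7 and 8, and 1145 without fluctuating high 6-cycle replicate 1. It was 384 and 471 without fluctuating low 12-cycle replicates 6 and 8, and 425, 372 and 362 without fluctuating low 6-cycle replicates 1, 2 and 3. Without the library with yolk transcripts it was 712, with 402 higher and 310 lower, of which 478 were among the 752.

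The fits of each cycle number share no libraries. In males at the high point 1663 genes were called the same way at 6 and at 12 cycles and 3 in opposite ways, with 241.6 the number that independent calls would share in the same direction. For the low point the numbers were 813 and 23 (219.7). In females they were 819 and 57 at the high (245.7) and 468 and 160 at the low point (237.2). Across genes, which are not independent replicates, the effects at 6 and 12 cycles correlated with Pearson's r of 0.495 and Spearman's rho of 0.612 in males at the high point, 0.377 and 0.4 at the low point, and 0.257 and 0.288 and 0.194 and 0.0805 in females.

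Whether the sexes respond differently was tested in 1 fit of all adults. At the high point Hsp70Aa responded more in males (2.21, adjusted p = 1.4e-09), as did TotA (2.03), TotC (1.96) and Hsp83 (0.56, adjusted p = 0.00487). Hsp68 (-1.75, adjusted p = 1.79e-11), Hsp23 (-0.59) and DnaJ-1 (-0.33, adjusted p = 0.00204) responded less. At the low point Hsp70Aa (1.43, adjusted p = 2e-05) and TotC (2.68, adjusted p = 0.00133) again had a more positive effect in males. Hsp68 (-0.97), DnaJ-1 (-0.48, adjusted p = 1.12e-05) and CG10570 (-5.08) had a more negative one. Yp1 was at -2.87 (adjusted p = 0.039), and at 0.60 without the library with yolk transcripts. A total of 1855 of 16058 genes differed at the high point (1029 more positive in males, 826 more negative) and 1209 at the low point (280 and 929, 364 and 601 with RLE factors, 607 and 936 with DESeq2). Of these 1548 and 1030 had at least 1 CPM in each sex. The count at the high point was 1213 without replicate 4 of every group, and at the low point 802, 750 and 637 without replicates 2, 5 and 7.

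Whether larvae respond differently from adults was tested in 1 fit of all 80 libraries. At the low point the effect was more positive in larvae for Hsp70Aa (4.26, adjusted p = 8.07e-11), DnaJ-1 (2.20, adjusted p = 3.8e-23), Hsp83 (1.85, adjusted p = 1.55e-14) and Hsp26 (0.77). At the high point the effect was more negative in larvae for Hsp70Aa (-3.03, adjusted p = 8.57e-07), Hsp83 (-1.08, adjusted p = 4.13e-07) and DnaJ-1 (-0.63, adjusted p = 5.48e-05). The effect on per at the low point was more negative in larvae (-1.56, adjusted p = 2.37e-04) and that on vri more positive (0.82, adjusted p = 3.37e-05). Those on cry (0.87) and tim (0.82) at the high point were more positive. A total of 2483 of 16306 genes differed at the high point (1487 more positive in larvae, 996 more negative, 1022 and 1221 with RLE factors, 1267 and 1440 with DESeq2). The low point gave 1828 (1183 and 645, 1040 and 830 with RLE factors). Of these 2123 and 1451 had at least 1 CPM in each stage or sex. The counts were 1284 without replicate 4 of every group at the high point and 1156 without replicate 3 at the low point.

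Genes called in several comparisons were counted against the number that independent lists of the same length would share. At the high point 67 genes rose in larvae, females and males (7.63 expected), among them Hsp23, the co-chaperone genes Cdc37 and Sgt1 and the proteasome gene Rpn3. There 55 fell in all (8.66 expected), among them Ldh, Pfk, Pgk, Idh3a, the basement membrane gene SPARC and the engulfment receptor gene drpr. Genes that rose in all at the low point numbered 7 (0.8 expected), including Hsp70Aa, Hsp70Ab and Hsp70Bb, and 4 fell (2.37 expected), including PPO3. Females and males shared 1837 genes in the same and 140 in the opposite direction at the high point (702.1 expected in the same) and 1542 and 100 at the low point (497.4). Larvae shared 202 and 43 with females and 187 and 57 with males at the high point (93.89 and 103.5 expected in the same direction), and 23 and 31 and 30 and 52 at the low point (18.03 and 26.01). With DESeq2 larvae shared 479 and 114 with females and 476 and 136 with males at the high point, and 71 and 90 and 78 and 127 at the low point. Between the points, 985 genes changed the same way in females and 438 in opposite ways (472.2 expected of each). The numbers were 1405 and 761 in males (769.8 and 769.7) and 16 and 10 in larvae (3.564 and 3.51), where both exceed expectation. In larvae ItgaPS4 (-2.22 at the high, -2.92 at the low point), PPO3 and alphaTub85E (-1.29, -1.58) fell at both points, whereas Hsp83 (-0.85, 1.24) and Kal1 (0.47, -0.59) changed in opposite directions.

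Of the 324 tests of lists, 130 were called with the preset correlation (60 higher, 70 lower) and 4 with the correlation estimated. The 4 are heat shock genes in larvae at the low point, in females at the high point and in the female difference between points, and the accessory gland list in larvae at the low point. The last rests on trace levels, and Acp36DE went from 0.389 to 1.46 CPM before scaling in females of that point and 6 cycles too. Fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes, called 78.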

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

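The tests of female RNA in a male library, and of exchanged point labels in larvae, were chosen after the results were seen; the splits of the libraries were planned before. In 128 groups of 4 libraries, a library was picked out where its gap to the nearest other library, as a share of the range of its group, exceeded Dixon's 95% critical value. Chance picks out about 1 in 20 groups. Total counts stood apart at 119 M (1000000 counts) in fluctuating females, high point, 6 cycles, replicate 2 and at 102.4 M in constant males, high point, 12 cycles, replicate 8, which also stood apart for vri (140.3 CPM). Hsp70Aa stood apart at 15.22 CPM in constant larvae, low point, replicate 4, at 56.09 CPM in fluctuating females, low point, 6 cycles, replicate 3 and at 16.73 CPM in fluctuating males, low point, 6 cycles, replicate 4. Hsp83 did at 3113 CPM in constant females, low point, 12 cycles, replicate 7 and at 795.1 CPM in constant males, high point, 6 cycles, replicate 1. Replicate 5 of fluctuating males at the low point and 12 cycles was picked out for Yp1 (64.74 CPM), Hsp70Aa (22.5 CPM) and Hsp83 (795 CPM), and replicate 4 of constant males at the high point and 6 cycles for Yp1 (4.32 CPM).

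Replicate 2 of constant males at the low point and 6 cycles was picked out for Yp1 (4635 CPM), Hsp70Aa (8.303 CPM) and Hsp83 (2090 CPM). RNA of a female fly in this library fits the male genes, of which 1136 lay at a median of 0.685 of the other libraries of the group (middle 50% from 0.658 to 0.715), and 44 female genes were at a median of 0.261 of the females of that point and cycle number; but 13 yolk and eggshell genes were at 2.63, above what any share of those females can bring, and this part stays open. A female library under a male label is ruled out by the same ratios, whose 25th percentile of 0.658 is far above the 0.05 set as the limit. Carry-over of reads at 1 common share from the female libraries of that point and cycle number is ruled out, since the ratios of 57 female genes to those libraries had a 75th percentile 7.91 times the 25th. No biological explanation was tested, since the design has no group for it.

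Heat shock genes rose in larvae at the low point, where the animals were cool, and the list was not called at the high point (adjusted p = 0.934), whereas it was higher at the high point relative to the low in females (adjusted p = 0.0493 with an estimated correlation) and in males, where the call was lost (adjusted p = 0.0826 with an estimated correlation). Exchanged point labels of the larval libraries could give this: of 51 genes whose treatment effect differed between the points in larvae and in 1 direction in both sexes, 26 went the opposite way in larvae and 25 the same way, which is 51% and lies between the limits of 75% and 25% set for the test, so it leaves the explanation undecided. The 11 genes of the heat shock and ER lists among the 51 include those that prompted the question, and 10 of them went the opposite way (Hsp83, DnaJ-1, Hsp70Ba, Hsp70Bb, Hsp70Bbb, Hsp70Bc, Gp93, Hsc70-3, Cnx99A and Droj2) and stv the same way, while of the other 40 genes 16 went the opposite way and 24 the same; without P58IPK, shv and CG7130, DnaJ-family genes outside the lists that all went the opposite way, the counts were 13 and 24 (35.1% opposite). Larval calls at the high point went with those at the high point in females (202 the same way, 43 opposite) and males (187 and 57) and against males at the low point (89 and 169), while larval calls at the low point also went with females (61 and 14) and males (70 and 16) at the high point, so these counts run both ways. A response of larvae that differs from that of adults by stage, the biological explanation the design gives, was not tested apart from the labels and stays open.

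Treatment effects differed between groups by tests of the difference itself, and other splits of the libraries were counted. The effect differed between the points for 247 genes in larvae (at most 2 in any of the other 34 splits), 2692 in females (at most 1271 in 99 drawn splits) and 3647 in males (at most 1451). Between 12 and 6 cycles it differed at the low point for 2825 genes in females (at most 299) and 752 in males (at most 346). At the high point it differed for 1158 genes in females (2 splits, the real one among them, reached it, highest 1626) and for 9 in males (3 did, highest 878). Why a split called more genes than the real one was not tested. Between males and females the effect differed for 1855 genes at the high point (at most 29 in the other splits) and 1209 at the low point (at most 261), and between larvae and adults for 2483 (at most 1098) and 1828 (at most 264). For the plain comparisons the highest other split gave 116 against 639 (larvae, high point), 2 against 162 (larvae, low point), 2 against 61 (larvae, constant), 418 against 4128, 1058 against 3082 and 2158 against 2846 in females, and 1711 against 5052, 2247 against 4829 and 933 against 1527 in males. In each of these only the real split reached its number, which excludes chance at a share of 0.05. For the differences chance stays open, as these splits exchange regimes.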

How the results depend on the processing

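The counts of genes were recomputed under each alternative, 1 choice changed at a time, and the cause of a change was not tested unless it is named. The comparisons of 6 or 12 cycles alone, the fit without the mixed-sex library and the values divided by 4 were chosen after seeing the data. The rest were planned. Counts within 1.5 times those reported were found for 30 of 30 results with RLE factors, 30 of 30 with values divided by 4, 16 of 16 without the mixed-sex library, 20 of 20 with the minimum count of 50, 19 of 20 with the robust fit and with no low-count filter, 25 of 30 with the replicate block and 19 of 29 with DESeq2.

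DESeq2 gave 1603 (larvae, high point), 524 (low point), 1407 (constant) and 1048 (difference between points), 16 for males at 12 against 6 cycles at the high point, 66 shared by the points in larvae, 479 and 71 shared by larvae with females at the high and low point, and 476 and 78 with males. Without the filter 0 genes were called in constant larvae, and 1 with the robust fit. A fit of the compared libraries alone gave 22, 253 and 753 in larvae (high, low, constant) and 667 in constant males. The fits of a single cycle number have fewer samples by construction. With 12 cycles alone females gave 1612, 1802, 604 and 1343 genes (high, low, constant, difference) and males 2773 and 1473 at the high and low point and 2315 for the difference; with 6 cycles alone the female difference gave 871, and males 2762 at the high point, 795 for constant and 2191 for the difference. A threshold of 0.01 is stricter by construction: larvae gave 98, 38, 0 and 35, females 2550, 1800, 1617 and 1467, and males 3353, 2790, 615 and 2311. The genes shared by the points were then 2, 484 and 688, those shared at the high point 26 (larvae and females), 24 (larvae and males) and 1033 (females and males), and at the low point 4, 7 and 780. Of the 130 list calls 4 were left with an estimated correlation, and fry gave 78.

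The replicate numbers were not taken to pair the samples, since not every pair of same-numbered libraries had a correlation over 0.1. The medians ran from -0.0144 to 0.0163. In larvae 9 of 24 pairs were over 0.1 and the range was -0.315 to 0.629. Of the libraries 6 of 16 larval, 4 and 0 of 16 female and 7 and 5 of 16 male libraries (6 and 12 cycles) correlated best with their own number. A replicate block in the fit gave 1037 genes in larvae at the high point and 766 in constant larvae, and 292, 18 and 12 shared by larvae with males at the high point, with males at the low point and with females at the low point. It moved no other count by over 1.5 times.

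With each library left out in turn, larvae gave 167 to 1162 genes at the high point, 44 to 270 at the low point, 0 to 1322 for constant and 75 to 640 for the difference. Females gave 3653 to 4244, 2739 to 3276, 2299 to 3113 and 2363 to 2948, and 567 to 1482 and 1945 to 3392 for 12 against 6 cycles at the high and low point. Males gave 4519 to 6049, 4079 to 5175, 1120 to 1865 and 3338 to 3844, and 5 to 11 and 362 to 1145. Males against females gave 1213 to 2033 at the high and 637 to 1369 at the low point, and larvae against adults 1284 to 2606 and 1156 to 1670, here with a replicate number left out of every group.

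Of the named genes, 110 of 117 in females at the high point, 96 of 106 at the low point, 112 of 119 and 108 of 123 in males, and 20 of 59 and 12 of 31 in larvae kept their call without any single library. Changes of direction arose in 3 settings. With 12 cycles alone, females gave AGO3 -0.017, Actn 0.007, ND-30 0.027 and blw 0.04 at the high point, Actn 0.067 and Rpn13 0.05 at the low point and Hsp23 -0.001 for constant. Males then gave TotB -0.032, TotX -0.35, Rpt3 0.048, Rpn13 0.055, blw 0.087, yellow-g 0.56, ndl 0.064, Yp2 1.44, dec 0.85, Vml 0.30 and Yp1 1.44 at the low point, and for the difference Vm26Aa -3.18, Vm34Ca -2.48, Cp38 -3.11, Yp2 -2.35 and Yp1 -2.11. With 6 cycles alone Fst was at -0.03 in females at the low point. Without the mixed-sex library Yp2 was at 0.53, dec 0.35, Vml 0.28, Yp1 0.73 and Hsp26 0.18 in males at the low point, and Yp1 at 0.60 for males against females; Hsp26 alone passed the threshold in its other direction (adjusted p = 0.0384). With values divided by 4, 1048 of 1063 named values kept side and direction. In larvae at the high point the values divided by 4 gave 688 calls against 639, and 32.8% of genes changed 1.5-fold were recovered in the simulated comparison. What depth limits was not separated from the spread between libraries.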

Other observations

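At constant temperature some groups of genes differed between the points beyond those given above. In females photoreceptor markers (13 higher and 2 lower at the high point; adjusted p = 2.59e-04; adjusted p = 0.762 with an estimated correlation), neuron markers (7 and 0; 8.36e-04; adjusted p = 0.762) and detoxification genes (29 and 8; 0.00677; adjusted p = 0.858) were higher at the high point and ER chaperones lower (1 and 9; 1.67e-05; adjusted p = 0.0826). In larvae detoxification genes (3 and 0; 34 and 1 adjusted over the list alone; 1.8e-11; adjusted p = 0.712) and glycolysis, glycogen and trehalose genes (3.52e-07; adjusted p = 0.686) were higher and proteasome genes lower (5.17e-06; adjusted p = 0.839). In males glycolysis, glycogen and trehalose genes (3 and 1; 4.7e-04; adjusted p = 0.682) were higher and photoreceptor markers lower (0 and 2; 0.00773; adjusted p = 0.924). The difference of the treatment effect between points was negative for cuticle proteins in larvae (8.87e-07; adjusted p = 0.68) and males (2 and 9; 0.00749; adjusted p = 0.0551; the groups with Sgs transcripts enter here) and for photoreceptor markers in females (1 and 9; 0.0209; adjusted p = 0.887), and positive for the female yolk and eggshell list (5 and 0; 0.0146; adjusted p = 0.924), each last p with an estimated correlation.

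Whole animals may differ between regimes in age or in the share of a tissue, and the limits of these 3 tests were set before the results were seen. For larval age, late third-instar genes had a median log2 fold change of 0.0681 at the high point (middle 50% from -0.349 to 0.242) and -0.139 at the low point; the limit for ruling age out was met, but the members go both ways, so the question stays open. A different share of ovary in females stays open. The germline median farthest from 0 was 0.0138, within the limit, but yolk medians were 1.07 and 0.316. A different share of testis and accessory gland in males stays open, with medians of at most 0.0705 for the testis list and of 0.292 and 0.30 for the accessory gland list at the high and low point. No biological explanation of these shifts was tested.

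Summed Sgs transcripts had a median of 11.5 CPM in the 8 constant adult libraries of the high point at 6 cycles and of 0.0529 in the other 56. Their source was not tested. Genes called in larvae at the high point shared 97 directions with those of females at the low point and opposed 64 (70 and 70 for independent calls). In larvae per was not called at either point (-0.63, adjusted p = 0.564, and -0.60, adjusted p = 0.664).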
